A study of Saccharolobus islandicus REY15A with 4 samples.

How the data were processed

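Total RNA from cells of Saccharolobus islandicus REY15A was depleted of ribosomal RNA and made into strand-marked (dUTP) libraries that were sequenced as paired ends on an Illumina HiSeq, per the labels' protocols. Libraries were grouped by the plasmid their labels name, pCsa3b (OE3b, 2 libraries) or pSeSD (Ep, 2 libraries). Nothing in the labels says whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. The submitters' processing notes list CASAVA, Bowtie2 2.2.3, HTSeq 0.6.1 and DESeq 1.18.0 without their roles or order. The genome build and the strand setting of the counting were not given in the sources used here, so a gene and an antisense partner cannot be told apart, and near-identical copies such as transposases may share reads. No coordinates are printed. Gene symbols and the order of genes came from RefSeq names for assembly ASM18955v1, in which 2652 of the 2806 locus tags were matched and 375 had a symbol.

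The main table holds FPKM values deposited by the authors, 1 column per library, per the file headers. The authors' deposited comparison tables hold log2 fold changes and p-values (raw and adjusted), per the file headers. Their names give the comparison as OE3b against Ep, while the headers of their read count columns call the second group WT. They list only genes with adjusted p up to 0.0498 and also carry the product text, so 950 of the genes have one. The 4 group columns of read counts in these tables were not used. Genes at 0 in all libraries numbered 86.

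The depth was read from the values: FPKM times gene length is a whole multiple of 1 step per library. Among values of up to 200 reads, 87.3% to 89.5% per library were whole within 0.01 reads, and the reads of 2687 genes were recovered, 99.65% to 99.74% of the total per library. A gene of 1 kb with 1 read has 0.352 and 0.283 FPKM in OE3b replicates 1 and 2, and 0.198 and 0.274 FPKM in Ep replicates 1 and 2. Counting intervals are exact 95% binomial intervals of the group's summed reads, and a floor of 3 reads over the group replaces a sum of 0. Both cover counting error only, since reads without molecular identifiers are not independent molecules. The replicates were distinct libraries: chi-square per degree of freedom between their reads was 23.2 for OE3b and 6.75 for Ep. Short RNAs such as tRNAs are poorly measured by libraries of this kind.

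Fold changes are differences of group means of log2(FPKM + 1), which understates the change of low genes. Genes with a mean FPKM of at least 1 over the 4 libraries were tested in limma 3.58.1 (lmFit and eBayes with trend, two-sided, R 4.3.3) with Benjamini-Hochberg adjustment at 0.05. Since the values are FPKM, count models were not used. An exact permutation test of single values cannot pass 0.05 with 2 against 2 libraries (6 splits, smallest two-sided p 0.333), so all p-values per gene come from limma. Gene lists were tested with camera (preset correlation 0.01, lists of at least 5 genes), with camera under an estimated correlation and with fry, adjusted within 2 families. Under an estimated correlation, camera takes its degrees of freedom from the libraries and not the genes. With so few libraries hardly any list could pass it, so a miss there does not show that correlation undoes a list. The first family holds the lists fixed before the data were examined, as rules on product text, symbol or locus tag. Product text turned out to exist for deposited genes only, so lists taken from product text alone were tested against genes with such text. The second family holds lists by gene symbol, ID or biotype. These were written after the tables were in hand and before the expression values were examined, apart from those of CRISPR genes in the deposited tables. A planned list of ATP synthase genes matched no gene.

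The genes named were set by a rule fixed beforehand. It took the genes matched as CRISPR-associated, among them the csa3 genes but not csaX SiRe_0771. The 10 largest rises and 10 largest falls were taken among called genes with a mean FPKM of at least 10 in a group. Both libraries of a group also had to lie apart from both of the other. Up to 4 called members of every other list passing camera were added. Genes outside the rule are said to be so. Runs of genes in which the libraries of a group differ were sought with a running median over 11 genes above 1 on the log2 scale, over at least 10 genes. This search, and the alternatives built on it, were added after the data were seen. Neighbouring calls were compared with 10000 shuffles.

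The test was tried on simulated libraries of 2525 genes modelled on OE3b against Ep. It recovered 31.3% of genes changed by 0.5 on the log2 scale, 75.8% of those changed by 1 and 87.5% of those changed by 2, with 1.56% of calls false, and found 1 planted run and none in the control. In the simulation 64 to 66 genes outside the planted run were changed at each size, and genes varied independently. The run's genes were left out of the false calls, so 1.56% does not carry over to the real libraries. Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter or a mean FPKM of at least 10, other scalings (the same sum per library as in TPM, median, quantile), other variance models, an adjusted p under 0.1, a stricter deposited p of 0.001, the replicate number as a block, and each library left out. With 1 library left in a group, limma pools the spread and that library is assumed to vary like the others. Added alternatives were the 2 runs left out, the 2 runs with OE3b replicate 2 raised by the run's median difference, limma-voom on recovered reads, and lists without csa3b. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.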

Results

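Transcript levels were measured by RNA sequencing in the thermoacidophilic archaeon Saccharolobus (Sulfolobus) islandicus REY15A, a model organism for CRISPR-Cas immunity in archaea. Cells carried either the plasmid pCsa3b (group OE3b, 2 libraries) or the plasmid pSeSD (group Ep, 2 libraries), and were grown at 75 °C in log phase to an optical density of 0.2. The comparison asks how the transcriptome, and the CRISPR-Cas genes in particular, differ between cells with the plasmid named for Csa3b, a Csa3 family transcription factor, and cells with the other plasmid. Values were FPKM, which scale the reads of a gene by its length and by the depth of the library, for 2806 genes, identified by locus tag. The reads behind them, recovered from the spacing of the values, came to 2838010 and 3530940 for OE3b replicates 1 and 2 and to 5059628 and 3653204 for Ep replicates 1 and 2. Pearson's r of log2(FPKM + 1) across genes was 0.976 between the OE3b libraries and 0.989 between the Ep libraries, against 0.921 to 0.934 across the groups.

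The csa3b transcript (csa3, SiRe_0765) stood far higher in both OE3b libraries. It reached 26336 and 22764 FPKM in OE3b replicates 1 and 2, against 24.9 and 26.8 FPKM in Ep replicates 1 and 2, a log2 fold change of 9.83 ± 0.11 (SE; limma, adjusted p = 3.5e-06). Reads of this gene made up 1.61% and 1.39% of all reads in the OE3b libraries and 0.0015% and 0.0016% in the Ep libraries. The other csa3 genes did not pass the test. SiRe_0764, which adjoins csa3b, measured 20.9 and 6.29 FPKM in OE3b against 17.9 and 19.5 FPKM in Ep (log2 fold change -0.64 ± 0.55, adjusted p = 0.39), and SiRe_0473 measured 49.5 and 73.9 against 62.8 and 82.0 FPKM (-0.24 ± 0.25, adjusted p = 0.47).

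Of 2663 genes tested, 581 were higher and 528 lower in OE3b than in Ep at a Benjamini-Hochberg adjusted p under 0.05 (limma), and 449 of these differed by a log2 fold change of at least 1. The balance of directions turned with the scaling, to 481 higher and 646 lower with the same sum per library (TPM), 546 and 588 with median centring, and 508 and 578 with quantile normalization. Besides csa3b, the largest rises were those of SiRe_0670 (zinc finger SWIM domain protein, log2 fold change 6.21 ± 0.16 SE), SiRe_0137 (putative transport protein, 6.16 ± 0.22), cedA SiRe_2100 (6.10 ± 0.15), SiRe_0269 (hypothetical protein, 5.84 ± 0.15), upsA SiRe_1881 (5.74 ± 0.13) and dps SiRe_0453 (5.73 ± 0.11), a ferritin-like protein that binds iron and protects DNA. SiRe_0454 (Rieske domain protein), SiRe_1957 (annotated as a flagellar hook protein) and SiRe_0187 (conserved hypothetical protein) followed with 5.58, 5.38 and 5.25. The dps transcript went from 97.4 ± 10.1 FPKM in Ep to 5199 ± 330.3 FPKM in OE3b (SD, n = 2 each).

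The 10 largest falls included genes with few or no reads in OE3b. SiRe_0872 (hypothetical protein, in the second of the runs of neighbouring genes described next) had no reads in either OE3b library and 24 and 14 reads in Ep replicates 1 and 2. Set against a floor of 3 reads over the group, it was 9.26-fold lower in OE3b. The exact 95% counting interval of its ratio of OE3b over Ep reached up to 0.139. Its neighbour SiRe_0873 fell from 123.1 ± 2.80 to 15.6 ± 4.78 FPKM (log2 fold change -2.94 ± 0.25), and SiRe_1883, which adjoins upsB, from 461.7 ± 18.7 to 52.5 ± 13.8 FPKM (-3.14 ± 0.20; SD, n = 2 each). SiRe_0998, a transporter of the major facilitator superfamily, fell by 2.67 on the log2 scale. SiRe_1502 had 2 reads in OE3b and 46 in Ep and the tRNA gene SiRe_t0025 had 1 and 18. Their ratios of OE3b over Ep were 0.059 and 0.076. The exact 95% counting intervals ran from 0.0070 to 0.227 and from 0.0018 to 0.481. The tRNA gene SiRe_t0012 and the genes SiRe_1102, SiRe_2448 and SiRe_1478 completed the set, with log2 fold changes of -3.58, -2.76, -2.41 and -2.36. Most calls were lost when an Ep library was left out, where the spread comes from the more variable OE3b pair alone. Without Ep replicate 1, 60 genes passed, and without Ep replicate 2, 59, among them the 10 largest rises in both cases and none of the 10 largest falls in either.

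The libraries of the OE3b group differed from each other over 2 runs of neighbouring genes, and this bears on several CRISPR genes. From SiRe_0564 to SiRe_0595, 29 of 29 tested genes were higher in OE3b replicate 1 than in replicate 2, with a median log2 difference of 1.74 (interquartile range 1.53 to 1.98). From SiRe_0743 to SiRe_0883, 125 of 126 tested genes were, with a median of 1.67 (1.33 to 1.91), csa3b not counted. The median over 2428 tested genes elsewhere was -0.03 (-0.20 to 0.16), and no such run was found between the Ep libraries. Against the Ep mean, the median gene of the 2 runs lay 0.60 and 0.37 higher in OE3b replicate 1 and 1.01 and 1.20 lower in OE3b replicate 2 on the log2 scale. Of the 155 genes tested in the runs, 4 rose and 5 fell in the test, and 146 were not called. These counts turned on the library: without OE3b replicate 1, 4 rose and 90 fell, without OE3b replicate 2, 46 rose and 17 fell, and without either Ep library none was called.

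**Figure D1:**
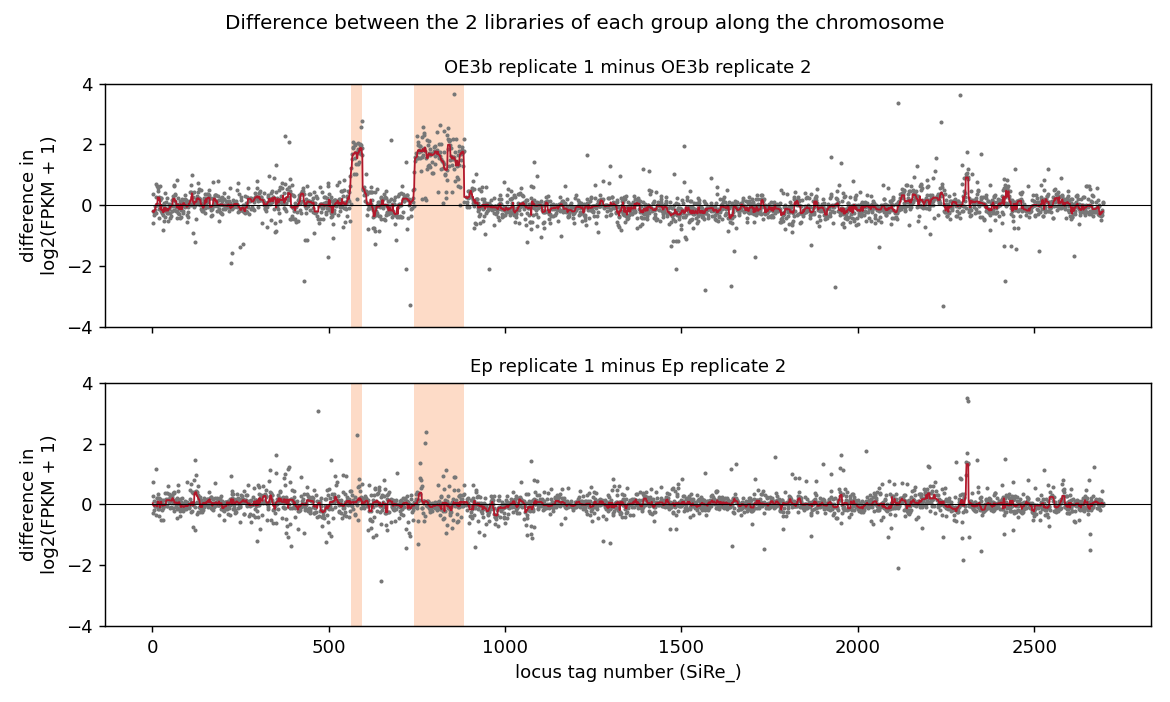
Difference in log2(FPKM + 1) between replicates 1 and 2 of OE3b (upper panel) and of Ep (lower panel) by locus tag number; each point is a tested gene, the line is the running median over 11 genes, and the shaded spans are the runs SiRe_0564 to SiRe_0595 and SiRe_0743 to SiRe_0883. In the upper panel the line lies between 1 and 2.1 across most of the shaded spans and near 0 elsewhere, while in the lower panel the spans do not stand out.

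The spacer acquisition genes cas1 and cas2 were higher in OE3b. The cas1 transcript (SiRe_0761), which encodes the integrase that inserts new spacers, measured 49.6 and 13.6 FPKM in OE3b replicates 1 and 2 and 3.62 and 2.19 FPKM in Ep, a log2 fold change of 2.82 ± 0.65 (SE; limma, adjusted p = 0.022). The cas2 transcript (SiRe_0762), which encodes the partner of Cas1, measured 10.4 and 4.20 against 0.732 and 0 FPKM (2.55 ± 0.68, adjusted p = 0.033). It rested on 12 reads in OE3b and 1 read in Ep, a ratio of 16.4 with an exact 95% counting interval from 2.43 to 701.8. A cas4 gene elsewhere on the chromosome, SiRe_1994, rose from 417.7 ± 22.4 to 796.4 ± 134.6 FPKM (SD, n = 2 each; 0.92 ± 0.14, adjusted p = 0.006). The other members of the list did not pass. The cas4 gene SiRe_0763 measured 29.4 and 5.36 against 4.49 and 2.59 FPKM (1.65 ± 0.80, adjusted p = 0.15), cas4a SiRe_0760 measured 8.68 and 2.33 against 2.32 and 1.61 FPKM (0.95 ± 0.67, adjusted p = 0.30), and cas4 SiRe_1245 had a log2 fold change of 0.21 ± 0.21 (adjusted p = 0.47).

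Thus 3 of the 6 adaptation genes rose, also 3 when adjusted over the list alone, and as a set the 6 did not pass camera, a test of a gene set against the other genes (adjusted p = 0.10, and adjusted p = 0.66 with an estimated correlation). The 4 genes SiRe_0760 to SiRe_0763 lie in the second run in which OE3b replicate 2 was low. Without OE3b replicate 2, the mean log2 fold change of the list went from 1.52 to 2.10 and passed camera (adjusted p = 0.020; adjusted p = 0.64 with an estimated correlation), with 5 of 6 genes called; without OE3b replicate 1 it was 0.93 and the call of cas2 SiRe_0762 was lost (adjusted p = 0.074). Without either Ep replicate 1 or Ep replicate 2, 0 of the 3 calls passed.

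The genes of type I-A interference, the complex that finds and degrades DNA with a matching spacer, did not pass the test in either direction. None of the 6 was called over all genes, with the list adjusted alone, at an unadjusted p under 0.05, or by limma-voom on the recovered reads. Their median log2 fold change was -0.60 (camera adjusted p = 0.375), and all 6 lie in the second run. The csa5 transcript (SiRe_0766) measured 295.3 and 81.3 FPKM in OE3b replicates 1 and 2 against 235.6 and 220.5 FPKM in Ep, and cas7a (SiRe_0767) measured 283.1 and 88.5 against 257.0 and 244.3 FPKM. The cas5a (SiRe_0768), cas3 (SiRe_0769) and cas6 (SiRe_0772) genes had log2 fold changes of -0.54 ± 0.84, -0.45 ± 0.80 and -1.21 ± 0.62. The direction of the list turned on 1 library, and with 1 OE3b library left the spread came from the Ep pair alone. With OE3b replicate 1 left out, the mean log2 fold change was -1.68 (camera adjusted p = 0.008; adjusted p = 0.66 with an estimated correlation) and 6 of 6 genes were called lower, and with OE3b replicate 2 left out it was 0.33 (adjusted p = 0.28) with none called.

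The genes of type III-B interference (the Cmr complexes, which act on RNA) were higher in OE3b. Of 11 genes in 2 clusters, 10 rose over all genes tested, and 10 when adjusted over the list alone, with a median log2 fold change of 1.10 (camera adjusted p = 0.00065; adjusted p = 0.66 with an estimated correlation). In the cluster SiRe_0597 to SiRe_0602, cmr4 (SiRe_0602) rose from 87.9 ± 12.4 to 257.8 ± 49.2 FPKM (SD, n = 2 each; log2 fold change 1.54 ± 0.18 SE, limma adjusted p = 0.0035) and cmr1 (SiRe_0600) from 72.4 ± 0.434 to 185.8 ± 31.7 FPKM (1.34 ± 0.16, adjusted p = 0.0034). The cmr3 gene SiRe_0597 was the one not called (0.50 ± 0.21, adjusted p = 0.11). In the cluster SiRe_0890 to SiRe_0894, cmr1 (SiRe_0892) rose from 80.2 ± 3.42 to 191.2 ± 11.4 FPKM (1.24 ± 0.12, adjusted p = 0.0022), and the smallest rise was that of cas10 SiRe_0894 (0.56 ± 0.14, adjusted p = 0.027), which encodes the large subunit. Without OE3b replicate 1, 9 of the 10 calls passed, and without OE3b replicate 2 all 10. Without either Ep library 0 of the 10 passed, while the mean log2 fold change of the list stayed at 1.06 and 1.02 and passed camera in both cases (adjusted p = 0.79 and 0.81 with an estimated correlation). The 2 clusters lie just past the ends of the 2 runs and outside them. In the first, SiRe_0597, SiRe_0598 and SiRe_0599 still differed by 0.57, 0.55 and 0.50 between the OE3b libraries (upper quartile outside the runs 0.16). The uncalled cmr3 SiRe_0597 had a log2 fold change of 0.78 without OE3b replicate 2. In the second, SiRe_0890, SiRe_0891 and SiRe_0892 differed by 0.27, 0.004 and 0.12.

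The gene next to the first Cmr cluster, SiRe_0603 (annotated Cmrx), rose from 374.4 ± 8.84 to 1031 ± 71.9 FPKM (SD, n = 2 each; log2 fold change 1.46 ± 0.09), a call lost without Ep replicate 1 and without Ep replicate 2 (adjusted p = 0.051 and 0.056). The list of genes matched as CRISPR-associated held 26, without csaX SiRe_0771. Of these, 15 rose and the rest did not pass, also 15 with the list adjusted alone (camera adjusted p = 0.0024; adjusted p = 0.66 with an estimated correlation). Without csa3b, 14 of 25 rose (camera adjusted p = 0.0098; adjusted p = 0.66 with an estimated correlation). Without Ep replicate 1, 1 of the 15 calls passed, and without Ep replicate 2, 1. The 14 neighbouring genes SiRe_0760 to SiRe_0773, taken by position, held csa3b, cas1 and cas2 as their calls and did not pass as a set (median log2 fold change -0.37, mean 0.99, camera adjusted p = 0.47); their mean was 1.82 without OE3b replicate 2 (adjusted p = 0.013; adjusted p = 0.64 with an estimated correlation) and 0.16 without OE3b replicate 1 (adjusted p = 0.26). Adjusted over the list alone, 2 of the 14 were called. With csa3b left out and all 4 libraries kept, 2 of 13 were called over all genes and 0 when adjusted over the list alone, with a mean of 0.31 and a median of -0.45 (camera adjusted p = 0.90).

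**Figure D2:**
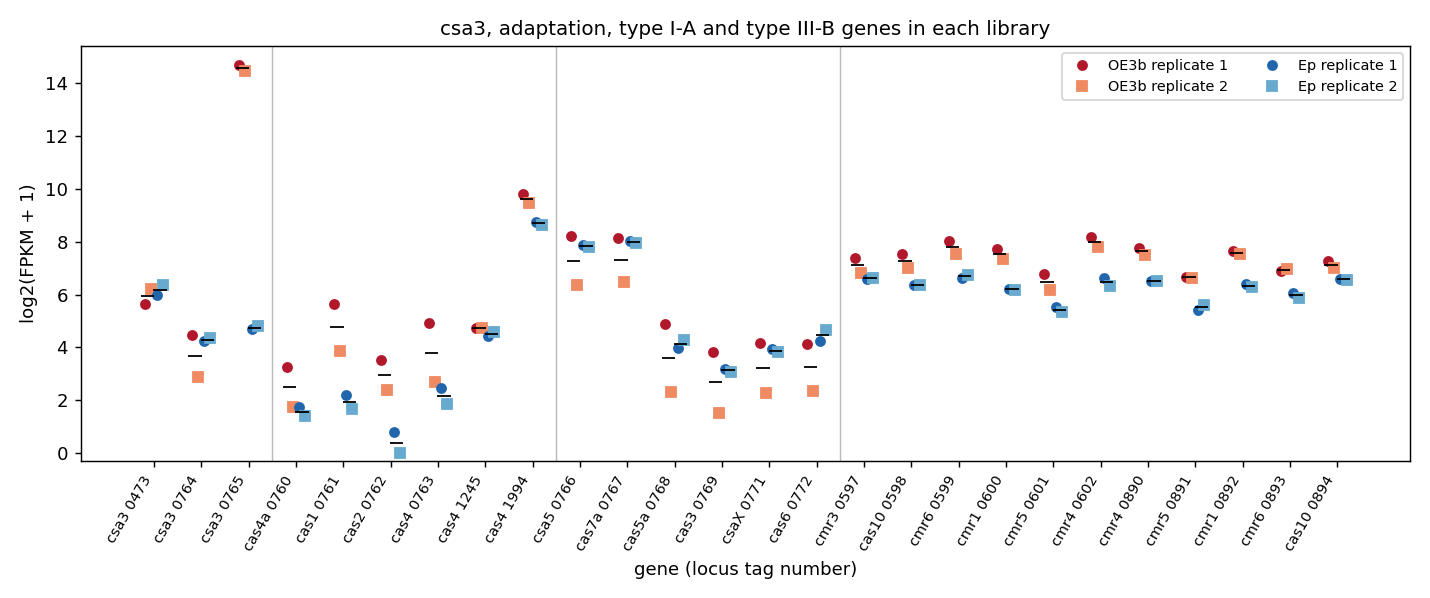
Level of the csa3, adaptation, type I-A and type III-B genes (separated by vertical lines, in that order) in each of the 4 libraries, as log2(FPKM + 1) by gene symbol and locus tag number; points are libraries and black bars are group means (n = 2). OE3b replicate 2 lies below OE3b replicate 1 in the genes from SiRe_0760 to SiRe_0772, and the OE3b libraries lie above both Ep libraries in all 11 type III-B genes.

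Genes of the Ups pili and the Ced system, through which Sulfolobus cells aggregate and take up DNA from one another, rose together. All 8 genes of this list were higher in OE3b, with a median log2 fold change of 4.39 (camera adjusted p = 2.3e-07; adjusted p = 0.60 with an estimated correlation), and all 8 calls passed with each of the 4 libraries left out in turn. The pilin gene upsA (SiRe_1881) went from 379.2 ± 58.8 to 20282 ± 1586 FPKM and cedA (SiRe_2100) from 19.8 ± 2.48 to 1426 ± 199.1 FPKM. The cedA1 gene (SiRe_1316) had a log2 fold change of 5.21 ± 0.18 (SE), and upsB (SiRe_1882) of 4.52 ± 0.27. This list was one of those written from gene symbols after the tables were in hand.

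Genes of the Cdv system, the ESCRT-III related machinery of cell division in this phylum, were lower in OE3b. Of 6 genes, 5 fell (median log2 fold change -0.71, camera adjusted p = 0.012; adjusted p = 0.60 with an estimated correlation). The genes annotated cdvB1/B2 fell from 8145 ± 172.1 to 3522 ± 456.5 FPKM (SiRe_1550, -1.22 ± 0.12 SE) and from 5982 ± 208.7 to 3591 ± 202.6 FPKM (SiRe_1200, -0.74 ± 0.09; SD, n = 2 each), cdvB3 (SiRe_1388) fell by 1.25 and cdvC (SiRe_1175) by 0.69 on the log2 scale. For cdvA (SiRe_1173) the log2 fold change was 0.01 (adjusted p = 0.93). Purine synthesis genes were lower as well, 8 of 10 (median -0.82, camera adjusted p = 0.00062; adjusted p = 0.60 with an estimated correlation). The purQ gene (SiRe_1380) fell from 666.0 ± 26.6 to 222.4 ± 14.8 FPKM and purC (SiRe_1382) from 1610 ± 1.27 to 725.8 ± 78.1 FPKM, and purS (SiRe_1381) and purF (SiRe_1378) had log2 fold changes of -1.44 and -0.86. Without Ep replicate 1, 0 of the 5 and 0 of the 8 calls passed; without Ep replicate 2, 0 and 1 passed. Both lists passed camera in each case (adjusted p = 0.80 and 0.88 with an estimated correlation, for both lists).

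**Figure D3:**
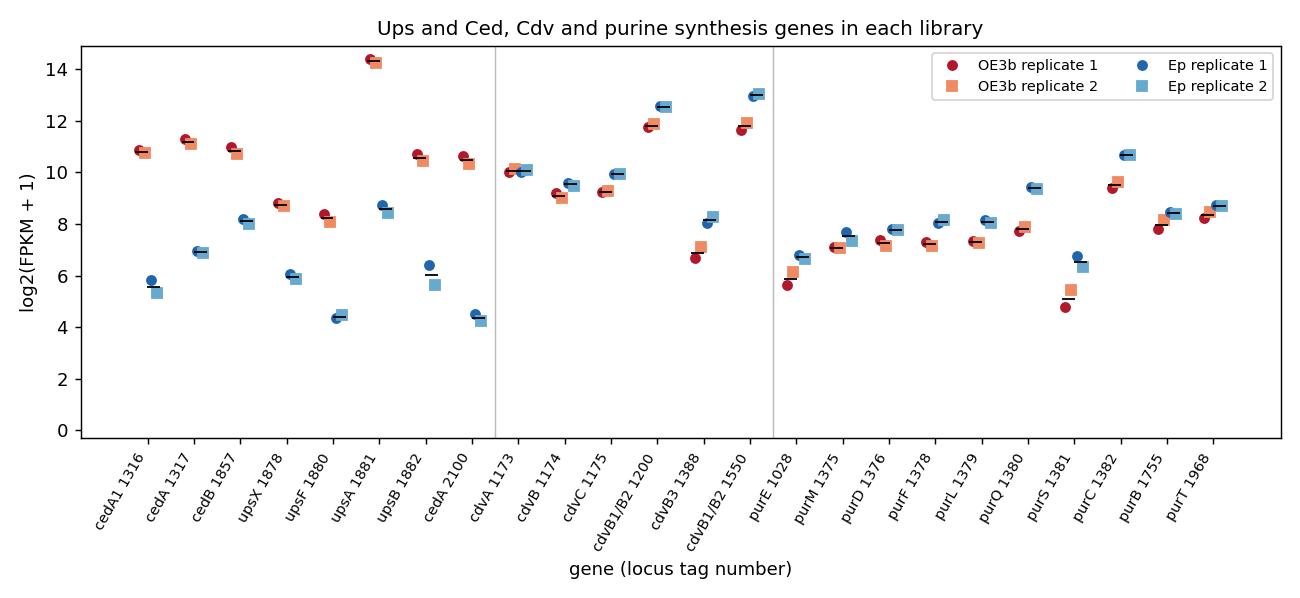
Level of the Ups and Ced, Cdv and purine synthesis genes (separated by vertical lines, in that order) in each of the 4 libraries, as log2(FPKM + 1) by gene symbol and locus tag number; points are libraries and black bars are group means (n = 2). Both OE3b libraries lie above both Ep libraries in all 8 Ups and Ced genes, and below them in all 10 purine synthesis genes and in the Cdv genes other than cdvA.

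Terminal oxidase genes, which encode the complexes that pass electrons to oxygen, included 5 that rose among 11 (median log2 fold change 0.57, camera adjusted p = 0.0014; adjusted p = 0.60 with an estimated correlation). These were soxL2 (SiRe_2437, 2.36 ± 0.11 SE), soxC SiRe_2550 (2.07 ± 0.14), soxB (SiRe_2549, 1.82 ± 0.11), soxA (SiRe_2548, 1.46 ± 0.13) and a further soxC, SiRe_2438 (0.99), named after its value was seen. Of the 5, 3 passed without Ep replicate 1 and 3 without Ep replicate 2. The soxB transcript went from 317.8 ± 39.5 to 1123 ± 13.8 FPKM (SD, n = 2 each). In the wider list of respiratory genes, 19 rose and 5 fell of 24 (camera adjusted p = 0.020; adjusted p = 0.66 with an estimated correlation), among them SiRe_1078, a complex I type gene (2.25 ± 0.31). Of 12 genes taken as citric acid cycle genes, 11 rose and 1 fell (camera adjusted p = 0.031; adjusted p = 0.66 with an estimated correlation), a call that was lost without Ep replicate 2 (adjusted p = 0.052). Its largest changes were in genes outside the cycle proper, fumarylacetoacetate hydrolases of aromatic compound breakdown (SiRe_0314, 2.41 ± 0.25; SiRe_2129, 1.05 ± 0.15), the isocitrate lyase of the glyoxylate shunt (aceA SiRe_0742, 1.83 ± 0.18) and a synthase of the isopropylmalate and homocitrate family (SiRe_0199, 0.96 ± 0.09). Among 39 transcriptional regulators other than Csa3, 10 rose and 29 fell (camera adjusted p = 0.031; adjusted p = 0.66 with an estimated correlation). The Fis family regulator SiRe_0302 (2.14 ± 0.20), the PadR-like SiRe_1956 (1.83 ± 0.13), the CopG domain protein SiRe_0197 (-1.65 ± 0.13) and the TetR family SiRe_0301 (1.57 ± 0.26) changed most. In these last 3 lists every gene is one the authors called. Product text was given for the genes in the authors' deposited tables, which were chosen on these same libraries, so the lists are not independent evidence of direction and were tested against the 950 genes with product text. Without Ep replicate 1, 5 of the 19 respiratory rises passed, 1 of the 11 rises of the cycle list and 1 of the 10 rises and 1 of the 29 falls of the regulators; without Ep replicate 2 these numbers were 5, 0, 1 and 0.

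Of 42 tRNA genes tested, 15 were lower and 1 higher in OE3b (median log2 fold change -0.51, camera adjusted p = 0.011; adjusted p = 0.60 with an estimated correlation). Besides those given, SiRe_t0032 fell by 2.27 and SiRe_t0039 by 2.08 on the log2 scale. With limma-voom on the recovered reads 11 of 41 were lower. None of the 15 calls passed without Ep replicate 1 or without Ep replicate 2. The 4 ribosomal RNA, signal recognition particle RNA and RNase P RNA genes tested, looked at as signs of ribosomal RNA removal, were not called by limma or limma-voom, and 1 was higher at an unadjusted p under 0.05. Among the 4 stable RNAs that carry product text, all of them tRNAs, 4 were lower, and of 4 genes annotated as viral, plasmid or integrase genes, 1 was higher and 3 were lower; these 2 lists also hold only genes of the authors' deposited tables.

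The authors' deposited tables list 961 genes, 471 higher and 490 lower in OE3b, with adjusted p up to 0.0498. All 961 had the same sign here, and 923 were also called (469 higher and 454 lower), with none called in the opposite direction. Across the 960 of these genes with a finite deposited fold change, the authors' log2 fold changes and those computed here had a Pearson's r of 0.996; genes are not independent replicates, and both come from the same libraries. A further 186 genes were called here and not listed in the authors' deposited tables, among them cas1 and cas2. For csa3b the authors' deposited table gives a log2 fold change of 9.87. Of the deposited genes, 17 lie within the bounds of the 2 runs: csa3b itself, listed as higher, and 16 listed as lower.

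Calls clustered along the chromosome. Of 2498 pairs of adjacent tested genes, 451 (18.1%) were called in the same direction, against 8.70% on average when calls were shuffled over the tested genes (one-sided permutation test, p = 0.0001, the smallest that 10000 permutations can give). Genes of an operon share a transcript, so single calls are not independent.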

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

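The tests with the 2 runs left out or rescaled, with limma-voom, without csa3b in the lists and with an estimated correlation for each library left out were chosen after the data were seen. The csa3b rise passed under every alternative (log2 fold change 9.57 to 9.94), as did the clustering of neighbouring calls. With each library left out in turn, calls ranged from 59 to 1189 (56 to 586 higher, 3 to 603 lower, 59 to 550 with a log2 fold change of at least 1, and 59 to 878 of the deposited genes). The lowest counts came without an Ep library, where the spread comes from the OE3b pair alone, which is the more variable pair and holds the 2 runs. Without an OE3b library it comes from the Ep pair alone, whose differences vary less (SD 0.34, against 0.41 in OE3b, outside the runs). Those calls judge a single OE3b library by that smaller spread. With the runs rescaled, 51 of their 155 genes were higher and 19 lower. Under the other alternatives, calls at an adjusted p under 0.05 ranged from 921 to 1338. Of the 528 deposited genes with a deposited adjusted p under 0.001, 526 were called. With the same sum per library (TPM), 42.7% of calls were higher, against 52.4%. Of 58 named genes called, 42 were lost without Ep replicate 1 and 42 without Ep replicate 2. Otherwise cas2 SiRe_0762 and SiRe_t0025 were lost at a pseudocount of 0.1, cas10 SiRe_0598 without the trend, and cas2 and cas10 SiRe_0894 without OE3b replicate 1.

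Of 5 planned lists passing camera, 0 passed with an estimated correlation (type III-B mean 1.04, adjusted p = 0.66), and fry called 14. The tRNA genes show the limit of the estimated form. Their estimated correlation, -0.0027, lay below the preset 0.01, yet their unadjusted camera p went from 0.0020 to 0.067. With a library left out, 9 to 13 lists of both families passed camera and 0 of them passed with an estimated correlation (lowest adjusted p = 0.64); noncoding RNA genes passed camera only without OE3b replicate 2 (adjusted p = 0.043; adjusted p = 0.79 with an estimated correlation). With the replicate number as a block, 1184 genes and 3 planned lists passed. The transcription regulators and the citric acid cycle list then missed the threshold (both adjusted p = 0.064), while glucose and maltose uptake (adjusted p = 0.040; adjusted p = 0.79 with an estimated correlation) and cas4 SiRe_0763 (adjusted p = 0.048) passed; no other list or named gene changed its call. The labels do not say that the numbers pair the libraries, and across all genes the deviations of same-numbered libraries had a correlation of 0.0245, though the genes SiRe_2307 to SiRe_2313 differ in the same direction between the replicates of both groups.

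The adaptation mean was 0.93 to 2.10 with a library left out and 2.01 with the runs rescaled, and passed camera without OE3b replicate 2 and with the runs rescaled (adjusted p = 0.020 and 0.027; adjusted p = 0.64 and 0.63 with an estimated correlation). With the runs rescaled, the 14 neighbouring genes taken by position had a mean of 1.68 and passed camera (adjusted p = 0.042, and 0.63 with an estimated correlation). The type I-A mean was -1.68 to 0.33 with a library left out and 0.067 with the runs rescaled. For 5 of its 6 genes and csa3 SiRe_0764 the log2 fold change crossed 0 over the libraries left out and with the runs rescaled, which by construction raises OE3b replicate 2 there: cas3 SiRe_0769 (-1.61 to 0.71, and 0.19), csa5 SiRe_0766 (-1.48 to 0.37, and 0.27), SiRe_0764 (-1.43 to 0.16, and 0.12), cas7a SiRe_0767 (-1.49 to 0.18, and 0.17), cas5a SiRe_0768 (-1.82 to 0.75, and 0.19) and csaX SiRe_0771 (-1.61 to 0.29, and 0.061). For cas6 SiRe_0772 it stayed negative (-2.10 to -0.32, and -0.48). Uncalled values near 0 crossed it too; the cause was not tested. With a library left out these were csa3 SiRe_0473 (-0.53 to 0.041), the tRNA synthetases (-0.071 to 0.011), aromatic amino acid synthesis (-0.095 to 0.11), branched-chain synthesis (-0.19 to 0.094) and chromatin proteins (lowest -0.0022). Aromatic synthesis also did so with TPM (-0.084), the median (-0.038) and quantiles (-0.042), chromatin proteins with TPM (-0.0045) and quantiles (-0.0035), and branched-chain synthesis with the runs rescaled (0.054). The count tools planned for read counts (edgeR, DESeq2, TMM) were not run, since the values are FPKM. Depth limits the low genes, such as cas2 with 12 reads in OE3b and 1 in Ep.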

Other observations

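The tests of the zones of the chromosome were set before their results were seen, after running medians had shown the zones; all other tests of explanations here were chosen after the result was seen, and so were the genes checked by hand.

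The 4 neighbouring genes nurA (SiRe_0061, log2 fold change 1.38), the Rad50-like SiRe_0062 (1.53), mre11 (SiRe_0063, 1.41) and herA (SiRe_0064, 1.29), named after their values were seen, were all called by limma, and radA (SiRe_1747), the recombinase, rose by 0.51, while the helicases of excision repair XPD (SiRe_1685) and Xpb1 (SiRe_1129) had log2 fold changes of -1.25 and -1.25. None of these calls passed without either Ep library. As a set, 5 of 11 repair and recombination genes rose and 2 fell (camera adjusted p = 0.48), and in the list from product text 6 of 8 rose and 2 fell (adjusted p = 0.30). Of 7 replication genes with product text, 2 rose and 4 fell (adjusted p = 0.47); the rises, SiRe_0614 and SiRe_0615, belong to the DNA polymerase B2 gene. By symbol 1 of 8 replication genes rose and 3 fell (adjusted p = 0.22).

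The remaining lists did not pass camera with all 4 libraries. Among those from product text, which hold only deposited genes, 7 of 8 ribosomal protein genes rose and 1 fell (adjusted p = 0.10), 4 of 10 translation factor and tRNA synthetase genes rose and 2 fell (0.75), 1 of 7 toxin-antitoxin genes rose and 6 fell (0.14), 5 of 7 chaperone genes rose and 2 fell (0.37), 7 of 9 sugar uptake genes rose and 2 fell (0.27), 32 of 57 transporter genes rose and 23 fell (0.45), 4 of 12 amino acid synthesis genes rose and 8 fell (0.37), and 14 of 18 genes matched by words for sulfur rose and 4 fell (0.096). Too small for the set test were the transposases (1 of 1 rose), basal transcription (2 of 4 rose and 2 fell), cell division (2 of 2 fell), pili (1 of 2 rose, 1 fell) and the proteasome (1 of 2 rose, 1 fell). Among the lists by symbol, ID or biotype, glucose and maltose uptake had 4 of 8 higher (adjusted p = 0.14), led by glcS (SiRe_2180, 1.14). The proteasome and exosome had 2 of 6 higher (0.18), chaperonins 3 of 7 higher and 2 lower (0.48), and ribosomal proteins 2 of 9 higher (0.28). Pyrimidine synthesis had 2 of 8 higher (0.95), tRNA synthetases 2 of 15 higher and 1 lower (0.70), and cobalamin synthesis 1 of 10 higher and 1 lower (0.25). Branched-chain amino acid synthesis had 1 of 8 higher and 2 lower (0.95), and lysine and arginine synthesis 2 of 8 lower (0.70). Chromatin proteins had 1 of 7 higher and 1 lower (0.95), noncoding RNA genes 6 of 33 higher and 11 lower (0.17), and pseudogenes 12 of 59 higher and 6 lower (0.48). The NADH dehydrogenase list, untested as a set, had 2 of 4 higher. No gene was called by limma or limma-voom in histidine synthesis (9 genes, 0 at an unadjusted p under 0.05), aromatic amino acid synthesis (8 genes, 1 at an unadjusted p under 0.05; adjusted p = 0.95), the CO dehydrogenase family (7 genes, 1; adjusted p = 0.41) and the tnpA transposases (3 genes, 0). The set test of histidine synthesis gave an adjusted p of 0.70.

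The 2 runs of genes that were low in OE3b replicate 2 ended between SiRe_0595, which differed by 2.78 between the OE3b libraries, and SiRe_0596 (0.50), and between SiRe_0883 (1.78) and SiRe_0884 (0.11), while the second began more gradually (SiRe_0742 0.52, SiRe_0743 1.11, SiRe_0744 1.45) and SiRe_0559 and SiRe_0560 before the first differed by 0.95 and 0.63. OE3b replicate 2 was not the shallower library (3530940 reads, against 2838010 in OE3b replicate 1). The median difference elsewhere was -0.032, but FPKM scaling holds it near 0, so it does not test the quality of OE3b replicate 2. Extra copies in OE3b replicate 1 would have left OE3b replicate 2 at its usual level, but its median against Ep was -1.01 in the first run and -1.20 in the second, below the lowest window of as many genes elsewhere (-0.59 and -0.26), while OE3b replicate 1 lay within the range of such windows. A candidate explanation is that part of the cells in OE3b replicate 2 had lost the DNA of both runs. That would lower every gene there by the same factor (to 0.299 and 0.315 of replicate 1) and spare a csa3b copy on a plasmid. Among genes with a mean FPKM of at least 10, the spread of the difference inside the runs was 1.21 times that outside. This lay within a bound of 1.5 set after the values were seen. Over all tested genes the quartiles lay further apart in the second run (1.33 to 1.91) than elsewhere (-0.20 to 0.16). The spread therefore does not decide for or against such a loss. Joint regulation of both runs in 1 culture stays open, as no DNA was analysed here, and it is the type I-A and adaptation genes whose values turn on it.

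The rise of the Ups and Ced genes resembles what Sulfolobus does after DNA damage, which may be at work in the OE3b cultures. Scaling would have to undo the rise, and the lowest log2 fold change of the 8 genes over the scalings tried was 2.65. Carry-over of chromosomal DNA adds about the same FPKM to every gene, and the 10th percentile of tested genes in OE3b came to 4.47% of the smallest rise among the 8. Of 4 other locus tags known from the damage response, checked after the result was seen, 4 rose. Over all genes tested, 581 of 2663 rose. The 4 were SiRe_1717, a TFIIB-type zinc finger protein (4.54), SiRe_1231 (2.49), SiRe_0615 (4.05) and SiRe_0614. SiRe_0615 and SiRe_0614 are parts of the same polymerase and not separate support. SiRe_0614 had 103 reads in OE3b and 2 in Ep, a ratio with an exact 95% counting interval from 19.0 to 589.5. Damage in these cultures and regulation by Csa3b itself cannot be told apart, since no library without damage, or with damage and without the csa3b rise, was analysed here.

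Rises were concentrated in zones of the chromosome outside the 2 runs. In windows of 51 tested genes, the highest mean log2 fold changes were 1.42 from SiRe_0297 to SiRe_0351 (35 genes higher, 1 lower) and 1.15 from SiRe_2186 to SiRe_2240 (35 higher, 1 lower), and the lowest was -0.54 from SiRe_1778 to SiRe_1830 (2 higher, 25 lower); in the first zone the OE3b libraries gave 1.49 and 1.35. The median log2 fold change was 0.59 in the lowest of 10 expression classes, where 28 of 243 genes were called higher. Shuffling fold changes among genes of like expression gave window means as variable as those seen in a share of 0.00010 of permutations. That is the smallest share that 10000 can give. Adjacent genes tended to be called alike and this shuffle parts them, so its outcome does not set low expression aside. Shuffling blocks of 10 neighbouring genes, cut at fixed places without regard to operons or expression, gave the same share, 0.00010. Operons across a cut were broken, so neither shuffle shows that more than operons and low expression is needed. A zone-wide cause is therefore a hypothesis, and differences in DNA content or base composition along the chromosome were not tested.

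Across 7 neighbouring genes, SiRe_2307 to SiRe_2313, which include sat, the ATP sulfurylase gene, and cobA, replicate 1 lay above replicate 2 in both groups: SiRe_2310 measured 34.3 and 9.44 FPKM in OE3b replicates 1 and 2 and 23.3 and 1.14 FPKM in Ep replicates 1 and 2.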
